A study of Rattus norvegicus with 84 samples.

How the data were processed

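Total RNA from the nucleus accumbens core and shell of Long-Evans rats was extracted with a column kit (Direct-zol), and libraries were made with a stranded total RNA kit for low input (SMARTer Stranded Total RNA-seq v3 Pico), per the labels' protocols. Such libraries also hold unspliced and non-polyadenylated RNA. The deposited counts are raw whole numbers per gene and library, made with featureCounts on the rat build mRatBN7.2, per the submitters' processing notes. The aligner, the annotation release, the strand setting and any use of molecular identifiers are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene therefore cannot be told apart, and values of gene families with near-identical copies are uncertain. The deposited FPKM values were made by the authors from the same counts: count and FPKM together imply 1 length per gene in every library for 100% of 21666 genes checked (within 1%). That length was 110527 bases for Mbp, 63986 for Drd2 and 2867 for Fos, which for the first 2 of these spans introns. FPKM was used only to obtain these lengths.

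The table held 41919 genes, of which 29367 identifiers matched RefSeq symbols of the rat. It had 0 blank entries and 0 unused columns. No pair of libraries was identical (0 pairs, highest correlation 0.996). Libraries held 13.6 to 22.5 M (mega) counts, and tests used the counts as deposited. The Y-linked genes Kdm5d and Eif2s3y had counts in 84 of 84 libraries. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples.

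Each library was placed in a group by its title, and replicates were named by the titles' own numbers. Choices made before the data were examined were the groups, the tests, the gene lists, the rule for named genes and a first set of other settings. Genes were kept by edgeR's filterByExpr (31370 in Core, 30911 in Shell, 32145 over all 84 libraries). They were scaled by TMM and tested with edgeR's two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Within a subregion all 42 libraries entered 1 fit with the series as an additive covariate, and 11 contrasts were taken: 3 drug contrasts, their average, 5 contrasts of conditions and 2 differences of drug effects. Shell against Core and its 3 interactions with drug used all 84 libraries, with F series against numbered series as a covariate. This makes 26 comparisons. Some genes that met the rule for naming are not reported here. Per-gene levels are log2 CPM, counts scaled to a common library total, with a prior count of 2. In each comparison the lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list and with fry. There were 31 lists: immediate early genes, markers of D1-type and D2-type projection neurons and interneurons, dopamine and cAMP signalling, neuropeptides, opioid and cannabinoid, glutamate and GABA genes, transcription and chromatin regulators, matrix, vesicle release, potassium channels, glia, vessels, choroid plexus, neighbouring cortex, blood, glucocorticoid, heat shock, clock and interferon genes, reported shell and core markers, and mitochondrial and ribosomal genes.

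Genes named in the text come from a fixed set. In each comparison it holds the 10 genes with the largest increase and the 10 with the largest decrease past an adjusted p of 0.05. These needed a mean log2 CPM of at least 1 and a symbol that is not an identifier. Where fewer than 10 passed it holds those and the 10 genes of lowest p, said not to pass where they did not. It adds up to 3 members of lowest p from each list and, for the drug comparisons, Fos, Fosb, Arc, Egr1, Npas4, Nr4a1, Bdnf, Drd1, Drd2, Pdyn, Penk and Cartpt. Any other gene is said to be named because its value was seen.

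That first set held DESeq2's size factors, DESeq2's Wald test, no low-count filter, no series covariate, only the groups compared, no F series, the F series alone, 2 surrogate variables from svaseq on scaled counts, and a replicate block. Others were added after the data had been seen. These were the background as a covariate (alone and with its square), subtraction of the background, only libraries with a log2 background level above 9, leaving out the Core Ctx_Coc library 17-F, and surrogate variables from unscaled counts, with and without that library. The background level is the log2 CPM summed over 1845 olfactory and vomeronasal receptor genes. The estimated background share multiplies their counts per base by the total gene length, and it rests on the assumption that such counts fall evenly over gene bodies.

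The numbers in the titles pair Core with Shell libraries (1-k with 3-k and 2-k with 4-k). For the 30 pairs, the correlation of deviations from group means, after removing 6 components over 200 genes, ran from 0.154 to 0.646 with a median of 0.411, against a median of -0.0159 for other pairings. All 30 lay above 0.1, and 23 of 30 libraries correlated best with their own number, so the numbers were taken to pair the samples.

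The scripts were tested on simulated data with known changes in the real libraries' means and sizes. For Core Ctx_Coc against Ctx_Sal (31370 genes) 56 of 100 genes changed 2-fold and 81 of 100 changed 4-fold were recovered, with 8 of 31142 unchanged genes called. For the same comparison in Shell (30911 genes) it was 88 and 100 of 100, with 8 of 30683 unchanged genes called. For Shell against Core (32145 genes) it was 96 and 100 of 100, with 9 of 31917 unchanged genes called. The simulated libraries lack the shared structure of the real ones. With no real difference and independent genes, 1568 of the 31370 Core genes would fall at an unadjusted p under 0.05. The same number is 1546 of 30911 in Shell and 1607 of 32145 over all libraries. Some comparisons gave far fewer, down to 53 in Core and 218 in Shell, so these counts by themselves do not measure signal. Other splits of the samples were drawn 70 times within a subregion, 50 times for Shell against Core and 25 times for its interactions, and drug labels were permuted 100 times for the correlations of drug effects. Exact permutation tests of single values were two-sided and kept the series. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.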

Results

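RNA was sequenced from the nucleus accumbens of Long-Evans rats, a striatal region whose core and shell subregions take part in reward and drug seeking. The labels give 2 subregions (Core and Shell), 3 conditions (Ext, HC and Ctx) and 2 drug groups (Coc for cocaine and Sal for saline). These make 12 groups of 7 libraries each, 84 in all. Ext stands for extinction in the study's own terms. In this field HC and Ctx commonly stand for home cage and context, which the labels do not state. The study set out to compare cocaine withdrawal with extinction in each subregion. Core libraries came in series 1, 2 and F and Shell libraries in series 3, 4 and F, as their titles number them. Each library held 13.6 to 22.5 M (mega) counts, with a mean of 17.2 ± 1.98 M (SD, n = 84). The mean was 17.4 ± 2.25 M in Core and 17.1 ± 1.68 M in Shell (SD, n = 42 each).

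Olfactory and vomeronasal receptor genes, which are silent in most neurons outside the nasal epithelium, served as a measure of counts that do not come from transcripts of the gene. Reads from unspliced RNA of expressed genes are not part of this measure. Counts of 1842 of the 1845 receptor genes rose with gene length, with a slope of 0.900 on log scales (95% interval 0.852 to 0.948), a little under proportion. Their rank correlation with length was 0.394. Spread over all gene bodies at the same rate per base, they gave an estimated background of 22.4% ± 14.0 of the counts of a library (SD, n = 84). Core libraries averaged 20.7% ± 17.6 and Shell libraries 24.1% ± 8.93 (SD, n = 42 each). Within Core the mean was 12.3% ± 10.1 in series 1 (n = 12), 28.4% ± 5.26 in series 2 (n = 18) and 17.6% ± 28.6 in series F (n = 12, median 3.97%). Within Shell it was 21.8% ± 4.94 in series 3, 27.3% ± 5.72 in series 4 and 21.8% ± 14.0 in series F. In the Core Ctx_Coc library 17-F the estimate was 100.6%, more than all of its counts, so it was too high there. Mitochondrial genes still held 0.576% of the counts of that library. With a slope under proportion, the rate of the receptor genes can overstate the background of longer genes. The percentages of other libraries may therefore be too high as well. The Drd1 level of 17-F was 7.72 CPM (counts scaled to a common library total). The mean over the 42 Core libraries was 64.1 ± 18.5. Differences of this background between the 6 groups did not pass a permutation test (p = 0.444 in Core, p = 0.140 in Shell).

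**Figure D1:**
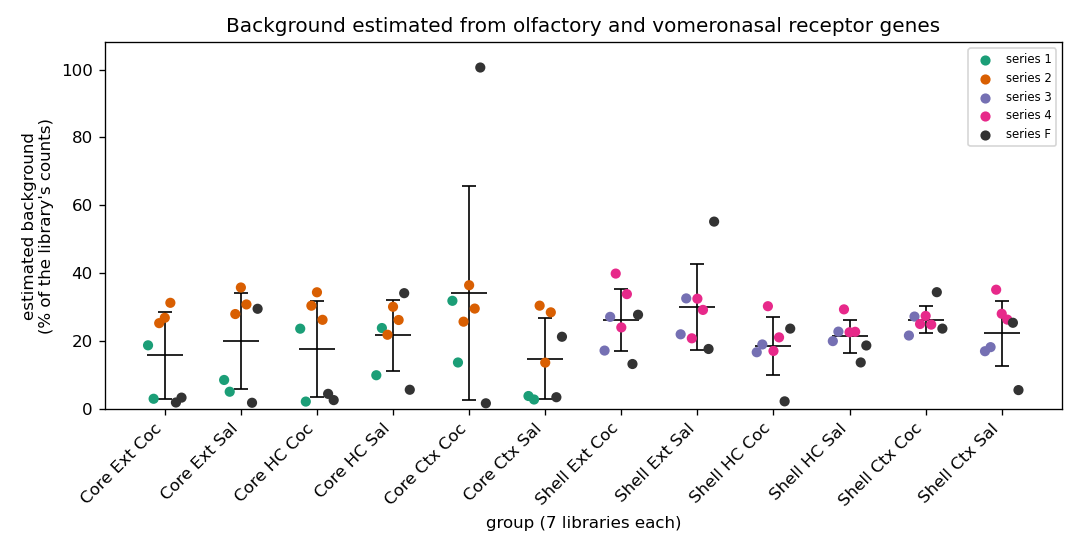
Estimated background of each library as a percentage of its counts (vertical axis), by group (horizontal axis, 7 libraries each). Points are libraries coloured by series, and bars are the mean ± SD. Core Ctx_Coc 17-F stands at 100.6%, an estimate above its total count, and the lowest library at 1.69%.

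Shell and Core were compared to ask how the subregions differ across drug and condition. Myelin genes were lower in Shell: all 14 measured members of the myelin list passed the test as lower, with a median log2 fold change of -1.72. Mobp, a myelin-associated protein of oligodendrocytes, stood at 7.99 ± 0.43 log2 CPM in Shell and 9.80 ± 1.03 in Core (SD, n = 42 each), a log2 fold change of -1.98 ± 0.15 (SE). Mbp (-1.82 ± 0.14), Mag (-1.75 ± 0.15) and Opalin (-1.74 ± 0.13) lay in the same range. For these 4 genes, 42 of 42 Shell libraries were below the Core mean. The 7 oligodendrocyte precursor genes were lower too, among them Gpr17 (-0.91 ± 0.13) and Bmp4 (-0.59 ± 0.07). So were the matrix genes Hapln2 (-1.38 ± 0.14) and Adamts4 (-1.34 ± 0.10), the latter a protease that cleaves aggrecan. Both oligodendrocyte lists passed camera, limma's test of a list against all other genes (adjusted p = 4.07e-42 and 7.43e-09), and both held with adjusted p = 0.00345 with an estimated correlation.

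Astrocyte genes went both ways. Gfap, an intermediate filament, was 3.06-fold lower in Shell (log2 -1.61 ± 0.17) and Aqp4, a water channel, 1.67-fold lower, while Agt, which encodes angiotensinogen, was 1.79-fold higher. Of the 12 astrocyte genes measured, 3 were higher and 2 lower over all genes tested (3 and 4 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.301). Of 14 microglial genes, 8 were lower (9 adjusted over the list alone), such as Trem2 (-0.34 ± 0.06) and Tmem119 (-0.35 ± 0.07). The microglial list was called lower at adjusted p = 7.80e-05, but at adjusted p = 0.172 with an estimated correlation.

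Among neuronal genes, several peptide and receptor genes were higher in Shell. Nmb, which encodes neuromedin B, was 2.15-fold higher (log2 1.11 ± 0.08), with 42 of 42 Shell libraries above the Core mean, and Nts, which encodes neurotensin, was 2.11-fold higher (1.08 ± 0.14). Drd3, the dopamine D3 receptor, was 1.59-fold higher (4.85 ± 0.19 against 4.17 ± 0.29 log2 CPM, SD, n = 42 each; adjusted p = 1.09e-17, edgeR). The opioid receptor genes Oprm1 (0.41 ± 0.04) and Oprl1 (0.62 ± 0.09) were higher, as were the glutamate receptor subunits Grin3a (0.42 ± 0.03) and Grik1 (0.62 ± 0.06). Tac1, a precursor of substance P, was 1.38-fold higher, and Penk, the enkephalin precursor of D2-type projection neurons, 1.92-fold lower. Higher levels were also found for Gpr165 (1.44 ± 0.16), Sertm2 (1.26 ± 0.13), the insulin receptor substrate Irs4 (1.24 ± 0.18), the potassium channel Kcnj16 (1.00 ± 0.11) and the mitochondrial glutamate carrier Slc25a18 (0.92 ± 0.06). Calb1, which encodes the calcium buffer calbindin, was 3.44-fold lower (-1.78 ± 0.15), and Cryab, a small heat shock protein, 3.87-fold lower.

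Interneuron markers leaned to Shell: 8 of 14 were higher and 2 lower, over all genes and adjusted over the list alone. Slc5a7, the choline transporter of cholinergic neurons, was 1.51-fold higher, Lhx8, a transcription factor of the same cells, 1.61-fold, and Calb2, which encodes calretinin, 1.45-fold. The list was called higher at adjusted p = 0.00102 (adjusted p = 0.122 with an estimated correlation). Of the 5 opioid and cannabinoid receptor genes 3 were higher (list adjusted p = 0.00565, and adjusted p = 0.122 with an estimated correlation). In the list of reported shell markers 3 of 5 were higher and 1 lower (2 adjusted over the list alone), with adjusted p = 0.0361 and adjusted p = 0.122 with an estimated correlation. Of the 2 reported core markers, 1 (Calb1) was lower (list adjusted p = 0.0135, and adjusted p = 0.123 with an estimated correlation).

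Further lists were called lower in Shell. Of 13 glucocorticoid response genes 7 were lower (10 adjusted over the list alone; list adjusted p = 1.66e-07, and adjusted p = 0.122 with an estimated correlation). Of 19 cocaine-linked transcription regulators 7 were lower (12 adjusted over the list alone), among them the kinase Camk4 (-0.68 ± 0.09) and the activity-dependent factor Egr3 (-0.82 ± 0.14); the list had adjusted p = 2.20e-05, and adjusted p = 0.369 with an estimated correlation. Counts of lower genes were 28 of 74 for cytosolic ribosomal proteins (61 adjusted over the list alone), 6 of 16 for the circadian clock, 7 of 16 for dopamine and cAMP signalling (9 adjusted over the list alone, with 1 higher) and 3 of 7 for D2-type neurons (5 adjusted over the list alone, with 1 higher). For these 4 lists adjusted p was 7.43e-09, 0.00102, 0.0284 and 0.0400, and adjusted p = 0.735, 0.725, 0.788 and 0.735 with an estimated correlation. Of 37 chromatin regulators 3 were lower and 1 higher (adjusted p = 0.00382, and adjusted p = 0.788 with an estimated correlation). Of 22 matrix genes 7 were lower and 3 higher; this list was called lower at adjusted p = 0.0284 (adjusted p = 0.122 with an estimated correlation), although its median was 0.01 and its mean -0.13. With the background as a covariate, a setting chosen after the data had been seen, 6 of the 15 list calls in Shell against Core kept call and direction: both oligodendrocyte lists, interneurons, opioid and cannabinoid receptors, reported shell markers and glucocorticoid response. Ribosomal proteins and chromatin regulators were then called higher (adjusted p = 0.0168 and 3.65e-06). With the covariate and an estimated correlation 4 lists were called: both oligodendrocyte lists lower (adjusted p = 0.00309 and 0.00866) and opioid and cannabinoid receptors (0.00610) and GABA genes (0.0434) higher. Interneurons, reported shell markers, glucocorticoid response, ribosomal proteins and chromatin regulators did not pass there.

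The remaining 16 lists did not pass. Over all genes tested, 5 glutamate receptor genes of 25 were higher and 9 lower, 5 GABA genes of 19 higher and 2 lower, and 4 potassium channel genes of 22 higher, such as Kcnc2 (0.58 ± 0.06), and 7 lower. Immediate early genes gave 2 higher and 5 lower of 28, D1-type markers 3 higher and 1 lower of 8, and neuropeptides 4 higher and 4 lower of 15. The counts adjusted over the list alone were 5 and 11 for glutamate receptors, 6 and 2 for GABA, 5 and 8 for potassium channels, 2 and 5 for immediate early genes, 4 and 1 for D1-type markers and 4 and 4 for neuropeptides. Vessel markers gave 2 lower of 10 endothelial genes and 2 higher of 12 mural and fibroblast genes (1 higher and 3 lower, and 5 higher and 2 lower, adjusted over the list alone). A single gene passed, over all genes, of 11 cortical glutamatergic (higher), 20 vesicle release, 10 heat shock and 19 interferon genes (lower in each of these 3), and 0 of 10 choroid plexus, 9 blood and 13 mitochondrial genes. In total edgeR's quasi-likelihood test called 1465 of 32145 genes higher and 2818 lower in Shell after Benjamini-Hochberg adjustment.

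Only the F series holds both subregions, so elsewhere the subregion cannot be told apart from the series. Within the F series (12 libraries each) the count was 21 higher and 67 lower. Of the 83 named genes 8 passed: Calb1 (-2.46), Cryab (-2.28), Gfap (-2.19), Ugt8 (-1.65), Adamts4 (-1.48), Nmb (1.24), Slc25a18 (1.06) and Drd3 (0.87). Mobp, Mbp, Mag and Opalin did not pass there, in a fit that keeps Core Ctx_Coc 17-F (Mobp at 5.30 log2 CPM). The F series was not fitted without that library. All 83 kept their direction in the F series. They were chosen in a fit that holds its libraries, so that is no independent check. The main fit does not pair the samples, and with the numbered libraries paired by a replicate block 78 of the 83 passed. Without Core Ctx_Coc 17-F the total was 8458 (4055 higher and 4403 lower) in place of 4283, with all 83 named genes passing in both fits. With the background as a covariate it was 13278 (9484 higher and 3794 lower), with 67 of the 83 past the threshold and 81 in the same direction. With 2 surrogate variables 14343 were higher and 3187 lower, and after subtraction of the background 2573 and 2061, so which direction holds more genes depends on the setting.

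**Figure D2:**
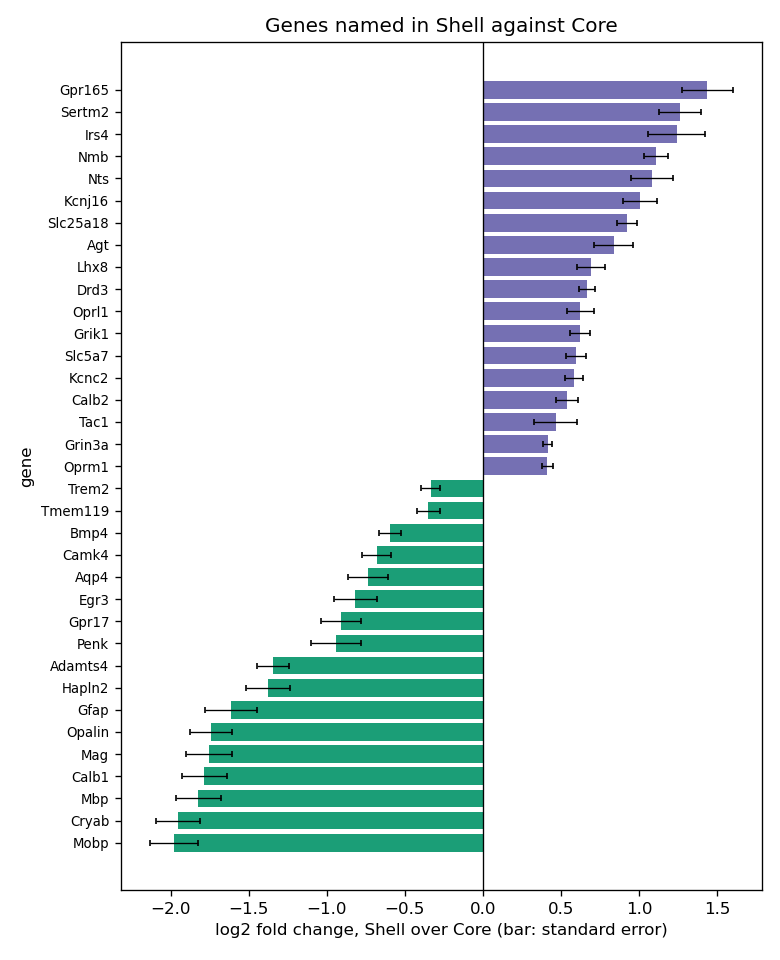
Log2 fold change of Shell over Core (horizontal axis) for genes named above (vertical axis), from 42 libraries of each subregion, with bars for the standard error. The range runs from 1.44 for Gpr165 to -1.98 for Mobp.

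In Shell, Ext_Coc was compared with Ext_Sal to ask how cocaine and saline groups differ in the Ext condition. Immediate early genes, transcribed within minutes of neuronal activity, had higher estimates in Ext_Coc for 27 of 28 members, with a median log2 fold change of 0.34. Egr2 was 1.47-fold higher (0.56 ± 0.19 SE; 7 of 7 Ext_Coc libraries above the Ext_Sal mean), Arc 1.65-fold (0.72 ± 0.27; 6 of 7), Egr1 1.51-fold (0.59 ± 0.24; 6 of 7), Nr4a1 1.41-fold (0.50 ± 0.18; 6 of 7) and Fos 1.42-fold (0.50 ± 0.21; 5 of 7). None of these 5 genes passed (adjusted p = 0.998 for each, edgeR), and 0 of 28 did so adjusted over the list alone. Penk had 0.50 ± 0.25, the lipoprotein lipase gene Lpl 0.47 ± 0.17, Syt10, a vesicle calcium sensor, 0.31 ± 0.11, and Trim34 -0.36 ± 0.10, with the same adjusted p. All 7 D2-type markers had positive estimates (median 0.31), and all 12 mural and fibroblast genes negative ones (median -0.41). camera called these 3 lists (adjusted p = 8.53e-16, 1.21e-05 and 0.000894), with adjusted p = 0.317, 0.373 and 0.419 with an estimated correlation. The background averaged 26.2% ± 9.15 in Ext_Coc and 30.0% ± 12.6 in Ext_Sal (SD, n = 7 each), with library 12-F of Ext_Sal at 55.2%. The comparison of Ext_Sal with HC_Sal below shares the Ext_Sal group on the opposite side, so the signs there and here are not independent. edgeR called 0 of 30911 genes (486 at an unadjusted p under 0.05, against 1546 for independent genes with no difference), and DESeq2 0.

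The Shell HC groups were compared in the same way. Mitochondrial transfer RNA genes had the highest fold changes: Trnd 9.50-fold higher in HC_Coc (log2 3.25 ± 0.71 SE; 5 of 7 libraries above the HC_Sal mean), Trnl2 4.83-fold (2.27 ± 0.59; 6 of 7) and Trnl1 3.44-fold (1.78 ± 0.40; 6 of 7). Single libraries set their means, with Trnd at 8.34 log2 CPM in 4-9 and Trnl2 at 7.66 in 14-F against group means of 3.22 and 3.03. Fosb had 0.20 ± 0.16 and the dopamine receptor gene Drd1 -0.04 ± 0.21, whose sign depended on the scaling (0.0023 with DESeq2's size factors). Adjusted p (edgeR) was 0.891 for these genes other than Drd1 (0.958). The test called 0 of 30911 genes (414 at an unadjusted p under 0.05; DESeq2 0).

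In Shell, several neuronal genes had lower estimates in Ctx_Coc than in Ctx_Sal. Nptxr, a neuronal pentraxin receptor, was 3.25-fold lower in Ctx_Coc (log2 -1.70 ± 0.42 SE), Olfm1 2.17-fold (-1.11 ± 0.31), Tp53i11 1.86-fold (-0.89 ± 0.22) and Nrip3 1.45-fold (-0.54 ± 0.14). Amph, an endocytic protein of synapses, had -0.38 ± 0.09, Brinp2 -0.43 ± 0.12 and the transcription factor Tcf4 -0.29 ± 0.08. For each of the 7 genes, 7 of 7 Ctx_Coc libraries were below the Ctx_Sal mean, and adjusted p was 0.731 (edgeR). The Ctx_Sal libraries were spread widely, Nptxr having an SD of 1.28 against 0.398 in Ctx_Coc. Of 11 cortical glutamatergic markers 0 passed over all genes and 6 were lower adjusted over the list alone (median -1.04; camera adjusted p = 0.0269, and adjusted p = 0.589 with an estimated correlation). In the same comparison camera called 12 of the 31 lists lower and 0 higher. With the background as a covariate 2 of these kept call and direction. The background averaged 26.3% ± 4.09 in Ctx_Coc and 22.3% ± 9.56 in Ctx_Sal (SD, n = 7 each). Fos had -0.29 ± 0.21 and Drd1 0.12 ± 0.21. The test called 0 of 30911 genes (1492 at an unadjusted p under 0.05), and DESeq2 called 1, RGD1563601, which was lower and is named only because its value was seen.

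Averaged over the 3 conditions in Shell, the inducible heat shock gene Hspa1b had 0.56 ± 0.17 (SE; 14 of 21 Coc libraries above the Sal mean), Fosb 0.24 ± 0.09 (14 of 21), the peptide precursor Cartpt 0.23 ± 0.13 (15 of 21), Pdk4, a kinase that restrains pyruvate dehydrogenase, -0.28 ± 0.09 (18 of 21) and Dock11 -0.15 ± 0.04 (19 of 21). Each had adjusted p = 0.9999 (edgeR). All 10 heat shock genes had positive estimates (median 0.06; camera adjusted p = 0.000281, and adjusted p = 0.467 with an estimated correlation), 1 of them passing adjusted over the list alone. edgeR called 0 of 30911 genes (289 at an unadjusted p under 0.05; DESeq2 0).

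The Core Ext groups were compared next, and the genes given here did not pass. Igf2, an insulin-like growth factor made by the meninges and choroid plexus, was 2.38-fold lower in Ext_Coc (log2 -1.25 ± 0.40 SE; 7 of 7 below the Ext_Sal mean), its binding protein Igfbp2 2.36-fold (-1.24 ± 0.45; 5 of 7), the amino acid transporter Slc6a20 1.56-fold (-0.64 ± 0.22; 7 of 7), Ranbp3l 1.74-fold (-0.79 ± 0.27; 7 of 7) and Cd74, an antigen presentation chaperone, 1.73-fold (-0.79 ± 0.28; 7 of 7). The Ext_Sal library 1-6 stood apart in Igf2 (6.29 log2 CPM against a group mean of 3.22), Ranbp3l (5.80 against 3.78) and Slc6a20 (5.61 against 3.96). Npas4 had 0.39 ± 0.20, Fos 0.38 ± 0.32 and Drd2 0.23 ± 0.27; Drd1 had 0.08 ± 0.37, with a sign that turned under several settings (-0.11 with the background as a covariate). Ranbp3l and Drd2 also turned in libraries of high background alone (0.02 and -0.01). Adjusted p was 0.923 for each of these genes except Drd1 (0.949), and edgeR called 0 of 31370 genes (180 at an unadjusted p under 0.05). DESeq2 called 1 gene, LOC102554537, lower and named only because its value was seen.

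The Core HC groups were compared as well. Rdh13, a retinol dehydrogenase, had 0.25 ± 0.08 (SE; 7 of 7 HC_Coc libraries above the HC_Sal mean), Acat2, a thiolase of sterol synthesis, 0.27 ± 0.11 (7 of 7), Nmb -0.54 ± 0.19 and Birc7, an inhibitor of apoptosis, -0.59 ± 0.22 (7 of 7 below for both). Drd2 had 0.30 ± 0.27 (-0.10 in libraries of high background) and Fos 0.27 ± 0.32 (-0.02 with the background as a covariate). Each of the 6 had adjusted p = 0.820 (edgeR). The 37 chromatin regulators had 35 positive estimates (median 0.16; camera adjusted p = 1.03e-06, and adjusted p = 0.551 with an estimated correlation), in groups whose background averaged 17.7% ± 14.1 in HC_Coc and 21.7% ± 10.4 in HC_Sal (SD, n = 7 each). Of the 31 lists camera called 15 higher there, and 0 of these kept call and direction with the background as a covariate. edgeR called 0 of 31370 genes (186 at an unadjusted p under 0.05; DESeq2 0).

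Ctx_Coc against Ctx_Sal gave the most genes at an unadjusted p under 0.05 of the 3 Core drug comparisons, 3407, with 0 of 31370 called by edgeR. Clec11a, a growth factor of bone and blood cells, was 1.63-fold lower in Ctx_Coc (log2 -0.70 ± 0.14 SE; adjusted p = 0.425, edgeR), Plcd1, a phospholipase C, 1.37-fold (-0.45 ± 0.10), Csf1, a growth factor of microglia, 1.35-fold (-0.43 ± 0.11) and Adcy1, a calcium-stimulated adenylyl cyclase, 1.36-fold (-0.45 ± 0.12), each with 7 of 7 libraries below the Ctx_Sal mean. The potassium channel subunit Kcnmb4 had -0.27 ± 0.07, turning to 0.04 once the background was subtracted. Fos had -0.61 ± 0.32, Arc -0.64 ± 0.42 and Drd1 -0.28 ± 0.38; Arc and Drd1 turned to 0.06 and 0.26 with 2 surrogate variables. All 14 myelin genes had negative estimates (median -0.55) and 27 of 28 immediate early genes (median -0.43); camera called both lists (adjusted p = 7.18e-06 and 6.13e-06), with adjusted p = 0.427 with an estimated correlation for each. Library 17-F of Ctx_Coc stood apart in Clec11a (1.52 log2 CPM) and in several genes of these lists (Mobp at 5.30, Fosl2 at 3.23, Egr3 at 1.40 and Arc at 1.08). Without it the mean of the immediate early genes differed by -0.28 in place of -0.52 (exact permutation p = 0.131 and 0.0861), and by -0.11 after subtraction of the background (exact p = 0.383). With the background as a covariate camera called neither list (adjusted p = 0.402 for myelin and 0.678 for immediate early genes). The background averaged 34.2% ± 31.6 in Ctx_Coc and 14.9% ± 12.0 in Ctx_Sal (SD, n = 7 each), and DESeq2's size factors moved the median of all genes from 0.03 to 0.14. DESeq2 called 2 genes lower, Clec11a and RGD1563601, the latter named only because its value was seen.

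Averaged over conditions in Core, Col25a1, a neuronal membrane collagen, had 0.17 ± 0.04 (SE; 21 of 21 Coc libraries above the Sal mean), the sorting receptor Sorcs3 0.17 ± 0.05 (19 of 21), Npas4 0.12 ± 0.11 (13 of 21), the chloride channel gene Best4 -0.37 ± 0.09 (21 of 21 below) and the transcription factor Foxp4 -0.14 ± 0.04 (20 of 21 below). None of the 5 passed, each at adjusted p = 1 (edgeR). The test called 0 of 31370 genes (434 at an unadjusted p under 0.05; DESeq2 0), and 2 surrogate variables taken from unscaled counts, tried after the data were seen, gave 3430, of which 0 were left without library 17-F.

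Conditions were compared within the drug groups to set extinction and Ctx against HC. The immediate early genes had lower estimates outside HC in several of these comparisons, Shell saline libraries among them. In Shell Ext_Sal against HC_Sal 26 of 28 members were negative, with a median of -0.51. Arc, a synaptic regulator, was 2.09-fold lower in Ext_Sal (log2 -1.06 ± 0.27 SE), Egr4 1.97-fold (-0.98 ± 0.27), Junb 1.83-fold (-0.88 ± 0.24), Fos 1.82-fold (-0.86 ± 0.21), Nr4a1 1.69-fold (-0.75 ± 0.18), Fosb 1.61-fold (-0.68 ± 0.17) and Fosl2 1.51-fold (-0.59 ± 0.13). For these 7 genes, 7 of 7 Ext_Sal libraries were below the HC_Sal mean; Fos stood at 2.63 ± 0.18 against 3.48 ± 0.27 log2 CPM (SD, n = 7 each). Over all genes 0 passed (adjusted p = 0.633 for each of the 7, edgeR), and 16 of 28 were lower adjusted over the list alone. camera called the list at adjusted p = 1.32e-20 (adjusted p = 0.117 with an estimated correlation), and fry, which asks only whether the members move one way, at 0.0199. All 16 dopamine and cAMP signalling genes (median -0.44) and all 7 D2-type markers (median -0.37) had negative estimates, and all 12 mural and fibroblast genes positive ones (median 0.69); adjusted p was 7.34e-12, 4.83e-06 and 0.000175, and adjusted p = 0.269 with an estimated correlation for each. The background averaged 30.0% ± 12.6 in Ext_Sal and 21.4% ± 4.77 in HC_Sal. Library 12-F of Ext_Sal stood apart at 55.2%, and the list means without it were not tested. Of the 31 lists camera called 3 higher and 16 lower, and 12 kept call and direction with the background as a covariate. The test called 0 of 30911 genes (1786 at an unadjusted p under 0.05; DESeq2 0).

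**Figure D3:**
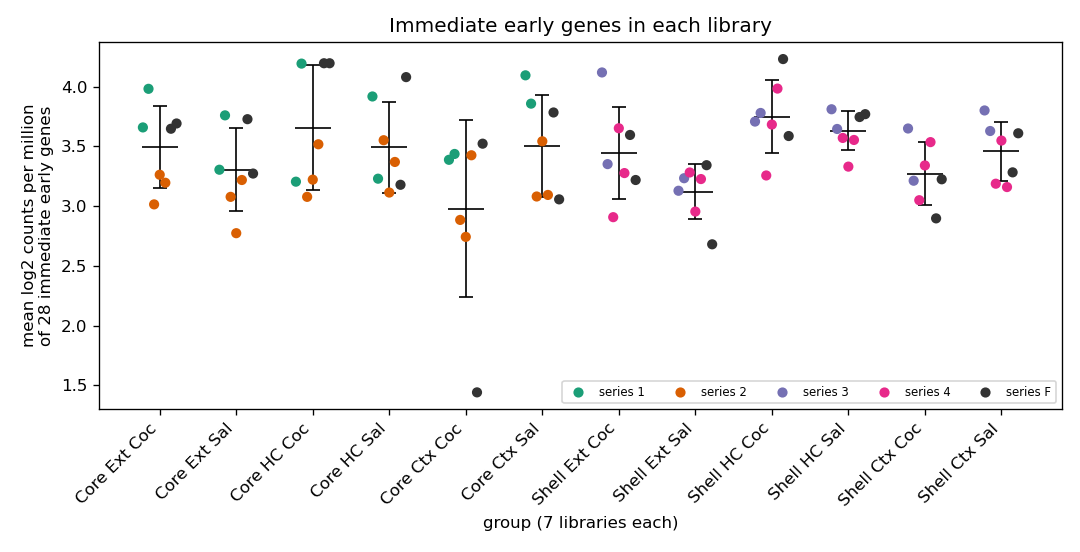
Mean log2 CPM of 28 immediate early genes (vertical axis) in each library, by group (horizontal axis, 7 libraries each). Points are coloured by series and bars are the mean ± SD; Shell Ext_Sal lies at 3.12 ± 0.23 and Shell HC_Sal at 3.63 ± 0.17.

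In Shell Ctx_Coc against HC_Coc the same list had 25 of 28 negative estimates and a median of -0.52. Fos was 1.96-fold lower in Ctx_Coc (log2 -0.97 ± 0.21 SE), the antiproliferative gene Btg2 1.85-fold (-0.89 ± 0.22), Nr4a3 1.70-fold (-0.77 ± 0.20), Nr4a1 1.63-fold (-0.71 ± 0.18) and Fosl2 1.495-fold (-0.58 ± 0.13), each with 7 of 7 libraries below the HC_Coc mean and adjusted p = 0.294 (edgeR). Over all genes 0 passed, and 18 of 28 were lower adjusted over the list alone. camera gave adjusted p = 7.95e-12 (adjusted p = 0.513 with an estimated correlation). Of the 31 lists camera called 16 lower and 0 higher, so lower estimates were not confined to this list. With the background as a covariate 2 of the 16 kept call and direction. The background was 26.3% ± 4.09 in Ctx_Coc and 18.6% ± 8.58 in HC_Coc (SD, n = 7 each). edgeR called 0 of 30911 genes (4921 at an unadjusted p under 0.05), and DESeq2 called 3, Fos and the mitochondrial transfer RNA gene Trnm lower and the epoxide hydrolase gene Ephx3 higher.

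Shell Ext_Coc against HC_Coc gave Klf2, a flow-responsive factor of endothelial cells, 1.90-fold lower in Ext_Coc (log2 -0.92 ± 0.27 SE; 7 of 7 below), the plasminogen activator gene Plat (-0.56 ± 0.15; 7 of 7), Fosl2 (-0.50 ± 0.13; 6 of 7) and the RNA-binding protein gene Msi2 (-0.29 ± 0.08; 7 of 7). Adjusted p was 0.464 for each (edgeR). The immediate early list had 25 of 28 negative estimates (median -0.36, 1 gene lower adjusted over the list alone; camera adjusted p = 6.15e-08, and adjusted p = 0.460 with an estimated correlation). Of the 31 lists camera called 14 lower and 0 higher, and 2 kept call and direction with the background as a covariate. Background averaged 26.2% ± 9.15 in Ext_Coc and 18.6% ± 8.58 in HC_Coc. edgeR called 0 of 30911 genes (2603 at an unadjusted p under 0.05; DESeq2 0).

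Between Shell Ext_Coc and Ctx_Coc, Phkg1, a phosphorylase kinase subunit, had -0.47 ± 0.10 (SE), Amph 0.41 ± 0.09 and Lig4, a DNA ligase, 0.71 ± 0.19, with 7 of 7 Ext_Coc libraries on that side of the Ctx_Coc mean. All 28 immediate early genes had positive estimates (median 0.20; camera adjusted p = 5.59e-08, and adjusted p = 0.636 with an estimated correlation). The 3 genes had adjusted p = 0.9999 (edgeR), and 0 of 30911 were called (218 at an unadjusted p under 0.05; DESeq2 0). In Shell Ctx_Sal against HC_Sal, Fosb was 1.47-fold lower in Ctx_Sal (-0.55 ± 0.16; 7 of 7), Sgsh, a lysosomal sulfatase, 1.59-fold lower (-0.67 ± 0.20), Tp53i11 1.72-fold higher (0.78 ± 0.22; 6 of 7) and Rasgrf2, a Ras exchange factor, 1.24-fold higher (0.31 ± 0.09), each at adjusted p = 1 (edgeR). Of 11 cortical glutamatergic markers 10 had positive estimates there (median 0.65; camera adjusted p = 0.00958, and adjusted p = 0.461 with an estimated correlation), as did 11 of 12 mural and fibroblast genes (0.00679 and 0.532) and 7 of 8 blood genes (0.00236 and 0.301). Of the 31 lists camera called 7 higher and 4 lower, and 0 with an estimated correlation. That comparison called 0 of 30911 genes (479 at an unadjusted p under 0.05; DESeq2 0).

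In Core Ctx_Coc against HC_Coc, 26 of 28 immediate early genes had negative estimates, with a median of -0.68. Fos was 2.18-fold lower in Ctx_Coc (log2 -1.13 ± 0.33 SE), Nr4a1 1.80-fold (-0.85 ± 0.25), Egr2 1.80-fold (-0.85 ± 0.26), Klf4 1.75-fold (-0.80 ± 0.19), Fosb 1.73-fold (-0.79 ± 0.25), Nr4a3 1.71-fold (-0.77 ± 0.21) and Fosl2 1.62-fold (-0.70 ± 0.18), with 7 of 7 libraries below the HC_Coc mean and adjusted p = 0.449 for each (edgeR). Over all genes 0 passed, and 9 of 28 were lower adjusted over the list alone; camera gave adjusted p = 2.16e-12 (adjusted p = 0.406 with an estimated correlation). Leaving out library 17-F of Ctx_Coc moved the difference of the list mean from -0.68 (exact permutation p = 0.0472, adjusted 0.189) to -0.34 (exact p = 0.114). The 14 myelin genes also had negative estimates (median -0.53; adjusted p = 1.51e-07, and adjusted p = 0.406 with an estimated correlation). Of the 31 lists camera called 17 lower and 0 higher there, and 5 kept call and direction with the background as a covariate. Background averaged 34.2% ± 31.6 in Ctx_Coc and 17.7% ± 14.1 in HC_Coc, and the median of all genes was 0.11, or 0.21 with DESeq2's size factors. edgeR called 0 of 31370 genes (1311 at an unadjusted p under 0.05; DESeq2 0).

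Core Ext_Coc against Ctx_Coc gave Lig4 2.12-fold higher in Ext_Coc (log2 1.08 ± 0.28 SE; 7 of 7), Ppp1r3g, a glycogen-targeting phosphatase subunit, 1.77-fold higher (0.82 ± 0.22; 7 of 7), and the adhesion receptor Adgrv1 (-0.52 ± 0.15; 7 of 7), the kinase Pik3cg (-0.54 ± 0.16; 6 of 7) and the cytokine Il18 (-0.45 ± 0.14; 6 of 7) on the lower side. Adjusted p was 0.304 for each of the 5 (edgeR). All 14 myelin genes had positive estimates (median 0.59; camera adjusted p = 1.61e-06, and adjusted p = 0.345 with an estimated correlation). Library 17-F of Ctx_Coc stood apart in Mobp (5.30 log2 CPM), and without it camera gave the myelin list adjusted p = 5.51e-07. Higher estimates were not confined to myelin, as camera called 17 of the 31 lists higher and 0 lower (19 called without 17-F). With the background as a covariate 5 of the 17 kept call and direction. The background averaged 15.8% ± 12.7 in Ext_Coc and 34.2% ± 31.6 in Ctx_Coc. The median of all genes was -0.18, or -0.30 with DESeq2's size factors. edgeR called 0 of 31370 genes (2986 at an unadjusted p under 0.05; DESeq2 0).

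Core conditions were also compared in the remaining 3 pairs. Ext_Coc against HC_Coc gave the interleukin gene Il4 (-0.49 ± 0.16 SE), the cytoskeleton-linking gene Ckap4 (0.40 ± 0.14), Gemin7, part of the machinery that assembles splicing particles (-0.27 ± 0.11), and the ciliary kinase Cilk1 (-0.69 ± 0.29, turning to 0.07 in libraries of high background), each at adjusted p = 1 with 0 of 31370 genes called by edgeR (109 at an unadjusted p under 0.05; DESeq2 0). Ext_Sal against HC_Sal gave contractile and matrix genes of vessel walls: Acta2 2.14-fold higher in Ext_Sal (1.10 ± 0.38; 5 of 7), Col1a2 2.04-fold (1.03 ± 0.37; 4 of 7; -0.11 in libraries of high background), Tagln 1.95-fold (0.96 ± 0.33; 5 of 7), Mgp 1.63-fold (0.70 ± 0.24; 5 of 7) and Myl9 1.55-fold (0.63 ± 0.23; 6 of 7), with Nr4a3 at -0.56 ± 0.21. Of 12 mural and fibroblast genes 3 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.56e-10, and adjusted p = 0.143 with an estimated correlation). Here camera called 14 of the 31 lists higher and 1 lower, and 4 kept call and direction with the background as a covariate. Library 1-6 of Ext_Sal stood apart in genes given here, with Col1a2 at 6.51 and Mgp at 3.87 log2 CPM against group means of 3.62 and 2.15. The 6 genes had adjusted p = 0.9999 (edgeR), and the test called 0 genes (72 at an unadjusted p under 0.05; DESeq2 0). Ctx_Sal against HC_Sal gave Nptxr 2.15-fold (1.10 ± 0.35; 6 of 7), Nrn1, a neuritin, 2.03-fold (1.02 ± 0.31; 6 of 7), the adrenergic receptor gene Adra2a 1.71-fold (0.77 ± 0.25; 5 of 7), Acat2 1.33-fold (0.41 ± 0.11; 7 of 7) and Adcy1 1.29-fold (0.37 ± 0.12; 6 of 7) higher in Ctx_Sal, at adjusted p = 0.890 each. Of 11 cortical glutamatergic markers 2 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00718, and adjusted p = 0.493 with an estimated correlation). The call was not confined to this list, as camera called 18 of the 31 lists higher and 0 lower. With the background as a covariate 3 of these kept call and direction. The background averaged 14.9% ± 12.0 in Ctx_Sal and 21.7% ± 10.4 in HC_Sal (SD, n = 7 each). edgeR called 0 genes (381 at an unadjusted p under 0.05), and DESeq2 0.

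Whether the drug effect itself depended on the condition was tested as a difference of effects. In Core, the Ctx effect minus the HC effect was -0.51 ± 0.15 (SE) for Plcd1, -0.68 ± 0.20 for Clec11a, -0.89 ± 0.27 for Klf4 and 1.02 ± 0.33 for the endothelial gene Emcn, at adjusted p = 0.351 each (edgeR), with a median over all genes of 0.16 (0.30 with DESeq2's size factors). The Ext effect minus the HC effect was -0.51 ± 0.20 for the matrix gene Sned1, -0.31 ± 0.13 for Cald1, which encodes caldesmon, and -0.33 ± 0.15 for the annexin gene Anxa5, at adjusted p = 1 each. For the 7 blood genes this difference was negative in 6, with a median of -0.69 (camera adjusted p = 0.000288, and adjusted p = 0.0367 with an estimated correlation; 0.998 by fry, and 0.980 with the background covariate and an estimated correlation). In Shell, the Ctx effect minus the HC effect was -2.09 ± 0.59 for Nptxr, -1.25 ± 0.32 for Tp53i11, -0.81 ± 0.23 for B2m, a subunit of MHC class I, -0.68 ± 0.17 for the small GTPase gene Rnd3 and -0.43 ± 0.12 for Tcf4 (adjusted p = 0.506 each). The Shell Ext effect minus the HC effect was -0.56 ± 0.16 for Rnd3 (adjusted p = 1). edgeR called 0 genes in each of the 4 (3712 and 53 at an unadjusted p under 0.05 in Core, 2441 and 241 in Shell), and DESeq2 0.

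Whether it depended on the subregion was tested the same way, as Shell minus Core. For Ctx the difference was 0.42 ± 0.11 (SE) for Rgs3, a regulator of G protein signalling, 0.53 ± 0.14 for Plcd1, 0.44 ± 0.12 for the serotonin receptor gene Htr1d and 0.90 ± 0.24 for Trim47 (adjusted p = 0.942 each, edgeR). Library 17-F of Core Ctx_Coc stood apart in Rgs3 (5.99 log2 CPM) and Trim47 (-0.16), and without it the list calls by camera in this comparison numbered 3 in place of 16. For HC it was 3.06 ± 0.73 for Trnd, 2.76 ± 0.67 for Trnl2 and -0.36 ± 0.14 for the receptor gene Il20ra (adjusted p = 1 each). Single libraries stood apart in these transfer RNA genes, Trnd at 8.34 log2 CPM in Shell HC_Coc 4-9 and Trnl2 at 7.66 in Shell HC_Coc 14-F, 2.30 in Core HC_Coc 13-F and 4.26 in Core HC_Sal 1-12. For Ext the difference was 1.48 ± 0.62 for Ttr, a transthyretin made by the choroid plexus, 0.46 ± 0.19 for Igfbp4 and -0.22 ± 0.09 for Foxn3 (adjusted p = 1 each). The 22 matrix genes had a median of -0.08 for Ext (camera adjusted p = 0.00281, and adjusted p = 0.0276 with an estimated correlation; 0.992 by fry, and 0.804 with the background covariate and an estimated correlation). edgeR called 0 of 32145 genes in each of the 3 (912, 114 and 160 at an unadjusted p under 0.05 for Ctx, HC and Ext), and DESeq2 0. These fits do not pair the samples. With the numbered libraries paired by a replicate block edgeR called 1 gene for Ctx, LOC120098722, higher and named only because its value was seen, and 0 for HC and Ext.

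Drug effects were also correlated across 30733 genes, which are not independent replicates, between conditions and subregions (9 pairs). Pearson's r was 0.764 for Core Ext with Core HC, 0.790 for Core HC with Shell HC, 0.683 for Core Ctx with Shell Ctx, 0.447 for Core Ext with Shell Ext and 0.386 for Shell Ext with Shell HC. It was negative for Core Ctx with Core HC (-0.730), Core Ext with Core Ctx (-0.624), Shell Ctx with Shell HC (-0.684) and Shell Ext with Shell Ctx (-0.359). Swapping drug labels within the groups 100 times gave a range from -0.838 to 0.869 for Core Ext with Core HC alone, and every one of the 9 values lay within the range of its own permutations. Adjusted permutation p was 0.545 for each Pearson and 0.525 for each Spearman correlation. Without library 17-F of Core Ctx_Coc the values for Core Ctx with Core HC, Core Ext with Core Ctx and Core Ctx with Shell Ctx were -0.436, -0.332 and 0.468. With the background as a covariate 5 of the 9 changed sign, these 3 among them (0.175, 0.237 and -0.0258).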

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

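The tests of the background, the mean score of the immediate early genes with its exact permutations, the values without library 17-F and the counts of splits were chosen only after the results had been seen, while the tests of neighbouring cortical tissue were set beforehand.

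The spread between libraries followed the background, and in Core the first principal component of the libraries' deviations held 78.6% of the variance and correlated with the background level at |r| = 0.988 (rho 0.980, and 0.984 without the 2 farthest libraries, n = 42). In Shell it held 59.7%, with |r| = 0.988 (rho 0.971, and 0.983 without those), and the permutation p was 0.0001 for each, the smallest the permutations can give. Sequencing depth stays open, since background and total count had a rank correlation of -0.338 (95% interval -0.515 to -0.134, n = 84), so libraries of more counts tended to hold less background, though depth was not varied apart from it. Genomic DNA in the libraries may be a source: the 11 Rhox genes, which lie on the single X chromosome of males, held a median of 0.464 of the receptor genes' counts per base (interquartile range 0.4412 to 0.4997) in the 42 libraries of highest background, near the 0.5 that male DNA would give, though the interquartile range stops just short of it, so this stays open. A dependence on drug or condition stays open too, since the lower of the 2 permutation p values for a group difference was 0.140, and a biological cause was otherwise not tested.

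Immediate early genes had lower estimates outside HC in several comparisons, 3 of which are weighed here, and of all 16 comparisons only Shell Ext_Sal against HC_Sal passed on the list mean, which fell by 0.511 on the log2 scale there, lower in 7 of 7 libraries (exact permutation p = 0.00278, the smallest that 720 splits allow, adjusted 0.0445), though camera with an estimated correlation gave 0.117. In Shell Ctx_Coc against HC_Coc it was lower by 0.474 (7 of 7, exact p = 0.0167, adjusted 0.133; camera 0.513), and in Core without 17-F by 0.335 (6 of 6, exact p = 0.114), against 0.681 with it (camera 0.406). Subtracting the background left -0.436 (exact p = 0.00556, adjusted 0.0889) and -0.366 (exact p = 0.0278, adjusted 0.111) in Shell, past 0.05 before adjustment but not after, and subtraction was incomplete, as the first principal component still followed the background (|r| = 0.884 in Shell, 0.923 in Core). With the background level as a covariate as well the Shell differences were -0.42 ± 0.12 and -0.34 ± 0.12 (SE). The subtracted list mean hardly followed the background (r = -0.123 in Shell), so that covariate could change little. On the counts as deposited, where r was -0.695, the covariate left -0.40 ± 0.10 and -0.26 ± 0.11 (SE). Both stayed below 0, which argues against background as the whole cause there, though the second shrank from -0.474. Core without 17-F gave -0.299 (exact p = 0.0833) after subtraction and -0.33 ± 0.12 with the covariate too (-0.31 ± 0.12 as deposited). Background cannot be told apart in Core, as the first of these did not pass. With the mean of the cortical markers as a covariate the differences were -0.491, -0.461 and, in Core without 17-F, -0.384 ± 0.18 (SE). In Shell these stayed near -0.511 and -0.474, which argues against neighbouring cortical tissue there as far as these markers track it. How closely the immediate early mean follows the cortical markers was not tested, so the covariate may have been able to change little. In Core the difference itself did not pass, so nothing is concluded there. Other neighbouring tissue was not tested. The condition itself may account for the pattern in Shell, untested beyond these data. Shell Ext_Sal holds library 12-F at 55.2% background, and the list mean without it was not tested.

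Nptxr, Olfm1 and other genes had lower estimates in Shell Ctx_Coc than in Ctx_Sal, none of them passing. In the 28 Shell libraries of the other 4 groups the 10 genes of lowest p had a median correlation of 0.688 with the mean of the cortical markers, against a median of 0.125 for single random genes, but Amph (0.297), Ephx3 (0.0596) and Kansl1l (0.0324) did not follow it closely. Neighbouring cortical tissue in some Ctx_Sal samples may therefore account for part of the difference, the cortical marker mean being 2.36 ± 0.27 in Ctx_Coc and 2.83 ± 0.92 in Ctx_Sal (SD, n = 7 each). After subtraction of the background the marker mean differed by -0.925 (exact permutation p = 0.186), so background cannot be told apart as a cause at this spread. A drug effect on the same genes was not tested apart from it.

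Other splits of the samples were counted for each comparison. Shell against Core called 4283 genes, and of 50 splits only the real one (1 of 50) gave as many, the highest of the others giving 1054. That share is the smallest that 50 splits allow, so chance is unlikely but not excluded. In the numbered libraries subregion and series coincide, so the splits cannot tell these apart. The other 25 comparisons called 0 genes, which any split matches (70 of 70 within a subregion, 25 of 25 for the interactions), so for them the splits say nothing about chance. The highest other split gave 0 genes in 15 of them, 1 in 5 and 5 in Shell Ext_Sal against HC_Sal. It gave 21158 for Core Ctx_Coc against Ctx_Sal, 21325 for the Core average, 4243 for Shell Ext_Coc against Ext_Sal and 5896 for the Shell minus Core effect in Ctx, which points to a structure of the samples apart from their groups.

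Single libraries stood apart from the other 6 of their group in 7 of 36 groups for library measures and in 64 of 720 for gene levels, where chance gives about 1 in 20. The total count was 14.1 M in Core Ext_Coc 9-F, 21.2 M in Core Ctx_Sal 21-F and 20.7 M in Shell Ext_Coc 4-3. The estimated background was 100.6% in Core Ctx_Coc 17-F, more than all of its counts, and 55.2% in Shell Ext_Sal 12-F. Mitochondrial genes held 3.30% of counts in Core HC_Sal 15-F and 2.84% in Shell Ext_Coc 2-F. The drug effect on blood genes differed between Core Ext and Core HC, with a median difference of -0.69, and that on matrix genes between Shell Ext and Core Ext, with -0.085, each by camera's test of the difference with an estimated correlation. Neither passed by fry (adjusted p = 0.998 and 0.992) or with the background covariate and an estimated correlation (0.980 and 0.804).

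The gene levels that stood apart are given in log2 CPM. Library 17-F of Core Ctx_Coc held 11 of them, Aqp4 at 3.51, Arc at 1.08, Clec11a at 1.52, Egr3 at 1.40, Fosl2 at 3.23, Gpr17 at 1.12, Grin3a at 6.21, Mobp at 5.30, Penk at 3.16, Rgs3 at 5.99 and Trim47 at -0.16. Core Ext_Sal 1-6 held 9, Anxa5 at 4.51, Cald1 at 6.92, Col1a2 at 6.51, Igf2 at 6.29, Mgp at 3.87, Myl9 at 4.30, Ranbp3l at 5.80, Slc6a20 at 5.61 and Sned1 at 6.18. Core Ext_Coc 1-F held 7, Col25a1 at 7.34, Grin3a at 5.37, Irs4 and Sertm2 at -2.38, Kcnj16 at -0.024, Nmb at 0.54 and Oprm1 at 5.06. Core HC_Sal 15-F held 4, Calb1 at 6.40, Nts at 3.82, Oprl1 at 3.27 and Penk at 9.08. In the other Core libraries they were Gpr165 at 3.07 in Ctx_Sal 1-18, Irs4 at -1.995 in Ctx_Sal 21-F, Igfbp4 at 2.68 in Ext_Coc 9-F, Acat2 at 3.64 in HC_Coc 1-9, Birc7 at 0.39 and Trnl2 at 2.30 in HC_Coc 13-F, Cald1 at 6.18 in HC_Coc 2-8, Trnl2 at 4.26 in HC_Sal 1-12 and Col1a2 at 3.61 in HC_Sal 2-11.

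Among Shell libraries Ext_Coc 3-2 held 5 such levels, Calb1 at 5.43, Gfap at 5.93, Kcnj16 at 2.43, Lhx8 at 2.48 and Syt10 at 5.33, and HC_Coc 6-F held 4, Calb2 at 4.74, Gpr17 at 4.67, Oprl1 at 4.46 and Rnd3 at 4.57. In HC_Coc there were also Trnl2 at 7.66 in 14-F, Slc5a7 at 3.37 in 3-8 and Trnd at 8.34 in 4-9, and in HC_Sal Hapln2 at 3.59 in 16-F, Egr4 at 3.67 and Tp53i11 at 3.86 in 3-11 and Kcnj16 at 3.14 in 3-12. In Ctx_Coc they were Fosb at 1.84 in 18-F and Nrip3 at 4.33 in 4-15, and in Ctx_Sal Oprl1 at 4.52 in 24-F, Bmp4 at 3.31 and Trim47 at 1.69 in 3-18 and Rasgrf2 at 6.93 in 4-17. In Ext_Sal they were Tmem119 at 1.12 in 12-F and Calb1 at 4.27 in 3-5.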

How the results depend on the processing

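The settings that use the background, leave out library 17-F or take surrogate variables from unscaled counts were chosen only after the data had been seen. Of 25 comparisons with 0 called genes, 18 gave 0 in every setting run. DESeq2's Wald test gave 1 gene in Core Ext_Coc against Ext_Sal (LOC102554537), 2 in Core Ctx_Coc against Ctx_Sal (Clec11a, RGD1563601), 1 in the same Shell comparison (RGD1563601) and 3 in Shell Ctx_Coc against HC_Coc (Fos, Ephx3, Trnm). A fit of only the groups compared gave 1 in Shell Ctx_Sal against HC_Sal (LOC120100308), and the background covariate 1 in Core Ctx_Coc against Ctx_Sal (Duoxa2). The identifiers and Duoxa2 were named after their values were seen. Surrogate variables from unscaled counts gave 1004 genes there (997 lower) and 3430 for the Core average (3358 lower), of which 4 (Clec11a, Duoxa2, LOC103692636, LOC120097949) and 0 were called without 17-F; the first variable correlated with the background at r = -0.988. The replicate block, which pairs Core with Shell libraries, gave 3534 genes for Shell against Core, with 78 of 83 named genes past the threshold, 1 (LOC120098722, higher) for the Shell minus Core drug effect in Ctx and 0 for the other 2 such effects.

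Shell against Core called 4283 genes (1465 higher, 2818 lower). The F series alone gave 88 (21 and 67), from fewer samples with 17-F among them. With 2 surrogate variables it was 17530 (14343 and 3187), and with those from unscaled counts 14464 (11895 and 2569). The background covariate gave 13278 (9484 and 3794) and the fit without 17-F 8458 (4055 and 4403). Counts within 1.5 times came from DESeq2's size factors (4298; 1231 and 3067), DESeq2 (4613; 1396 and 3217), no filter (4046; 1777 and 2269), no series covariate (3948), no F series (3136) and subtraction (4634; 2573 and 2061). Of the tests of gene lists camera called 327 of 806, and 4 with an estimated correlation, 14 with fry, 169 with the background covariate and 4 with both the covariate and an estimated correlation, so most list calls rest on the preset correlation. With the background covariate 5 correlations of drug effects reversed: Core Ext with Core Ctx (0.237), Core Ctx with Core HC (0.175), Shell Ext with Shell HC (-0.0754), Shell Ext with Shell Ctx (0.0490) and Core Ctx with Shell Ctx (-0.0258).

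Of 2082 values of the 164 pairs of a gene and a comparison printed in the report 2019 kept direction and side of the threshold, 28 lost and 12 gained a call, and 23 reversed. The wider set of 83 named genes in Shell against Core was less stable: 8 passed in the F series alone, 67 with the background covariate, 68 after subtraction, 70 with surrogate variables from unscaled counts and 75 without the F series. Drd1 in Core Ext_Coc against Ext_Sal reversed to -0.024 without the F series, -0.051 with 2 surrogate variables, -0.12 with those from unscaled counts (-0.11 without 17-F), -0.11 with the background covariate, -0.11 with its square added, -0.10 in high-background libraries and -0.037 after subtraction. High-background libraries alone also reversed Ranbp3l (0.025) and Drd2 (-0.010) there, Drd2 (-0.10) and Fos (-0.19) in Core HC_Coc against HC_Sal, Cilk1 (0.072) in Core Ext_Coc against HC_Coc and Col1a2 (-0.11) in Core Ext_Sal against HC_Sal. Fos in Core HC also gave -0.021 with the background covariate and -0.035 with unscaled surrogate variables without 17-F. In Core Ctx_Coc against Ctx_Sal, Kcnmb4 gave 0.037 after subtraction, Arc 0.061 with 2 surrogate variables and 0.060 with the covariate and its square, and Drd1 0.26 and 0.23 with the same 2 settings. Drd1 in Shell HC_Coc against HC_Sal gave 0.0023 with DESeq2's size factors and 0.0027 with DESeq2. The cause was not tested for any of these reversals. At this depth and spread 2-fold changes were recovered in 56 of 100 simulated genes in Core and 88 in Shell in simulated libraries without the shared structure of the real ones, and smaller changes were not simulated.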

Other observations

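The exact permutations of the mural gene mean were chosen only after the list results had been seen.

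Genes of vessel walls had estimates of one sign in 2 Shell comparisons of the extinction groups, without passing on their mean. In Shell Ext_Sal against HC_Sal all 12 mural and fibroblast genes had positive estimates (median 0.69), and in Ext_Coc against Ext_Sal all 12 had negative ones (median -0.41). Both share the Ext_Sal group, on opposite sides, so a few high Ext_Sal libraries would give opposite signs by themselves; the SD of the list mean was 0.705 in Ext_Sal and 0.108 in HC_Sal (n = 7 each). The mean of these genes was higher by 0.416 in Shell Ext_Sal than in HC_Sal (exact permutation p = 0.286, adjusted 0.842 over 16 comparisons) and differed by -0.288 between Ext_Coc and Ext_Sal (exact p = 0.483, adjusted 0.842). In Core the same contrasts, which share Ext_Sal too, gave 0.296 (exact p = 0.389) and -0.251 (exact p = 0.392). None of the 4 differences passed. Library 1-6 of Core Ext_Sal stood apart in Col1a2, one of these genes, and the mean without it was not tested.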
